A study of Homo sapiens with 8 samples.

How the data were processed

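RNA-seq and ribosome profiling were deposited for cells labelled THP-1 that had been transduced with wild-type DNMT3A or with a DNMT3A mutant. Per the labels' protocols, total RNA was extracted with TRIzol and copied to cDNA with oligo(dT) for the mRNA libraries. Footprints were made with RNase I, selected by size on a gel, depleted of ribosomal RNA and built with a kit for small RNA. Sequencing was paired-end on an Illumina instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample labels, which give 2 libraries for each of the 4 combinations of genotype and assay. The labels do not say that replicates came from separate cultures.

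The deposited values are whole-number counts of reads per Ensembl gene, not normalized, with 1 library per file. The submitters' processing notes name cutadapt, Trimmomatic, Bowtie2, STAR and featureCounts and the builds hg38 and GRCh38, without the role or version of each tool. The annotation release, the strand setting, the counted feature (exon or coding sequence) and the treatment of reads that match several places are not given in the sources used here. Without them, reads of near-identical copies, of overlapping genes and of antisense partners cannot be assigned with certainty, and the values of ribosomal protein, histone and globin genes and of FTH1, EIF4A2 and PRSS2 are uncertain for that reason. No reference genome was used here, so GC content was not examined. Each library listed 20453 gene IDs, of which 20407 matched a symbol in the reference name table, 46 did not and 7 shared a symbol with another ID. Coordinates are those of GRCh38.

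Total counts per library lay between 3415999 and 4523475 for mRNA and between 603360 and 1988513 for footprints. The shallower mutant footprint libraries give the least precise values. Floors of 3 counts cover counting error only, while standard errors cover counting error and the spread between libraries. Reads without molecular identifiers are not independent molecules.

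Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood method (glmQLFit with legacy set to FALSE, where the installed default is TRUE, and glmQLFTest), with TMM factors computed within each assay and genes kept by filterByExpr with genotype as the group. The mRNA comparison used the 4 mRNA libraries and the footprint comparison the 4 footprint libraries. Footprints per mRNA were tested as the interaction of genotype and assay in 1 model over 8 libraries, for genes kept in both assays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 3 comparisons were adjusted separately. Gene lists, 39 in all, were fixed before the data were examined, as were the main tests and the first set of alternatives. Lists with at least 5 measured members, 34 in each comparison, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. Each was tested again with the correlation estimated from the residuals and with fry. With the estimated correlation no list passed in any comparison: camera called 0 lists, the lowest adjusted p was 0.431 in mRNA, 0.581 in footprints and 0.251 in footprints per mRNA, and lists with an unadjusted p under 0.05 numbered 1, 0 and 5.

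Genes were named by a rule: DNMT3A; then, among called genes with a mean count of at least 100 in each assay used and both mutant values on the same side of both wild-type values, the 8 largest rises and the 8 largest falls of each comparison; then up to 4 members with the smallest p of each list described. Marker genes given only as levels were picked from the lists after their values were seen. A few genes are not reported here. Shares of counts by gene class were compared by an exact permutation test, two-sided, which with 2 against 2 libraries cannot give a p under 0.333.

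The procedure was tested on simulated counts drawn from the real means and library sizes with 200 changed genes. With a coefficient of variation of 2% between replicates, as estimated here, genes changed 2-fold were recovered in 83.7% of cases in mRNA (10755 genes tested), 71.4% in footprints (9135 genes) and 70.2% in footprints per mRNA (9104 genes). Genes changed 1.5-fold were recovered in 58%, 40.8% and 24%. False calls were 2.84%, 2.68% and 4% of all calls. With a coefficient of variation of 10%, 2-fold changes were recovered in 90%, 46.9% and 43.8% of cases. Simulated data without any change gave 0 edgeR calls and 0 called lists in each comparison. A simulated trend with gene density and no other change gave 1203 mRNA calls and 215 footprint calls, and 0 of each after removal of the trend. The same simulated trend gave 5 called lists in mRNA and 1 in footprints, and 0 of each after its removal. A list of aminoacyl-tRNA synthetases shifted 1.3-fold in simulated data had an adjusted p of 0.0751 (mRNA) and 0.0509 (footprints) with an estimated correlation, so that test missed a shift of this size.

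Alternatives planned in advance were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a mean count of at least 100, each library left out in turn, the replicate number as a block, a 2-fold threshold, mitochondrially encoded genes left out, the legacy quasi-likelihood method, TMM over all 8 libraries and a limma test of paired ratios. Where a left-out library leaves a group with a single library, that library is assumed to vary like the others. Chosen after seeing the data were a likelihood ratio test with an assumed biological coefficient of variation of 10%, the thinning of the footprint libraries to the smallest total of 603360, and the removal, in each library, of a spline trend (4 degrees of freedom) in the number of protein-coding genes starting within 500 kb and in gene span. Local density was known for 96% of listed genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.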

Results

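Transcript levels and ribosome occupancy were compared between cells transduced with wild-type DNMT3A and cells transduced with a DNMT3A mutant. DNMT3A is a de novo DNA methyltransferase that is recurrently mutated in acute myeloid leukaemia. The cells were labelled THP-1, a human line established from acute monocytic leukaemia. RNA-seq counted mRNA, and ribosome profiling counted the short mRNA fragments that ribosomes protect from nuclease (footprints). The 8 libraries formed 4 groups of 2: wild-type mRNA, mutant mRNA, wild-type footprints and mutant footprints. Total counts were 3415999 and 4523475 in the wild-type mRNA libraries (replicates 1 and 2), 4393445 and 3901659 in the mutant mRNA libraries, 1611724 and 1988513 in the wild-type footprint libraries, and 944824 and 603360 in the mutant footprint libraries. Between 11156 and 13136 genes had a count in a library. A floor of 3 counts stood for 0.663 to 0.878 counts scaled to a common library size (CPM) in the mRNA libraries and for 1.51 to 4.97 CPM in the footprint libraries, which covers counting error only. All fold changes are mutant over wild type, and each mean ± SD in CPM is over n = 2 libraries.

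DNMT3A itself (ENSG00000119772, GRCh38 chromosome 2, 25227874 to 25342590) was measured first. Its mRNA stood at 288 and 290 CPM in the wild-type libraries and at 244 and 246 CPM in the mutant libraries. The fall of -0.27 on the log2 scale (SE 0.053) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 4.3e-06). Its footprints were 142 ± 10.8 CPM in wild-type and 148 ± 3.37 CPM in mutant libraries (edgeR log2 fold change -0.003, adjusted p = 0.992), a difference whose sign turned with the scaling. Footprints per DNMT3A mRNA had a log2 fold change of 0.26 (edgeR interaction, adjusted p = 0.254). Gene counts do not separate the introduced copy from the cell's own gene, so these values do not check which allele was carried. The mRNA call was lost when a biological coefficient of variation of 10% was assumed (edgeR adjusted p = 0.27), and the fall was -0.41 once the trend with local gene density was removed.

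Marker genes of several lineages were read as levels in all 8 libraries. Globin and erythroid regulator transcripts were abundant: HBG2 (a fetal gamma globin) stood at 507 ± 15.1 CPM in wild-type and 498 ± 20.7 CPM in mutant mRNA, and GATA1 (the master transcription factor of erythroid and megakaryocytic cells) at 432 ± 1.59 and 401.8 ± 1.27 CPM. KLF1, another erythroid transcription factor, stood at 303 ± 7.81 and 221 ± 31.8 CPM. Between 12 and 14 of 18 erythroid and megakaryocyte markers reached 10 CPM in each of the 8 libraries. Of 38 monocyte and macrophage markers, between 7 and 10 reached 10 CPM in a library. FCGR2A, APOE and CTSB led them, and SPI1, LYZ, CD68, CD80 and CD36 followed. In the 4 mRNA libraries 17 monocyte markers had no count, among them S100A8, S100A9, FCN1, CD163, CSF1R and IRF8, which allows each at most the floor given above. Markers of epithelial cells were present too, with KRT8 at 349 ± 4.02 and KRT18 at 415 ± 13.9 CPM in wild-type mRNA. Of 16 T and NK cell markers 2 reached 10 CPM in the mRNA mean, one of them CD3D at 61.7 ± 3.68 CPM in wild-type mRNA. None of 12 B cell markers, 12 fibroblast and endothelial markers or 13 MHC class II genes did, each count being 0. Of 14 granule protein genes of myeloid progenitors 3 reached 10 CPM, and 7 had no mRNA count in any library, MPO among them.

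**Figure D1:**
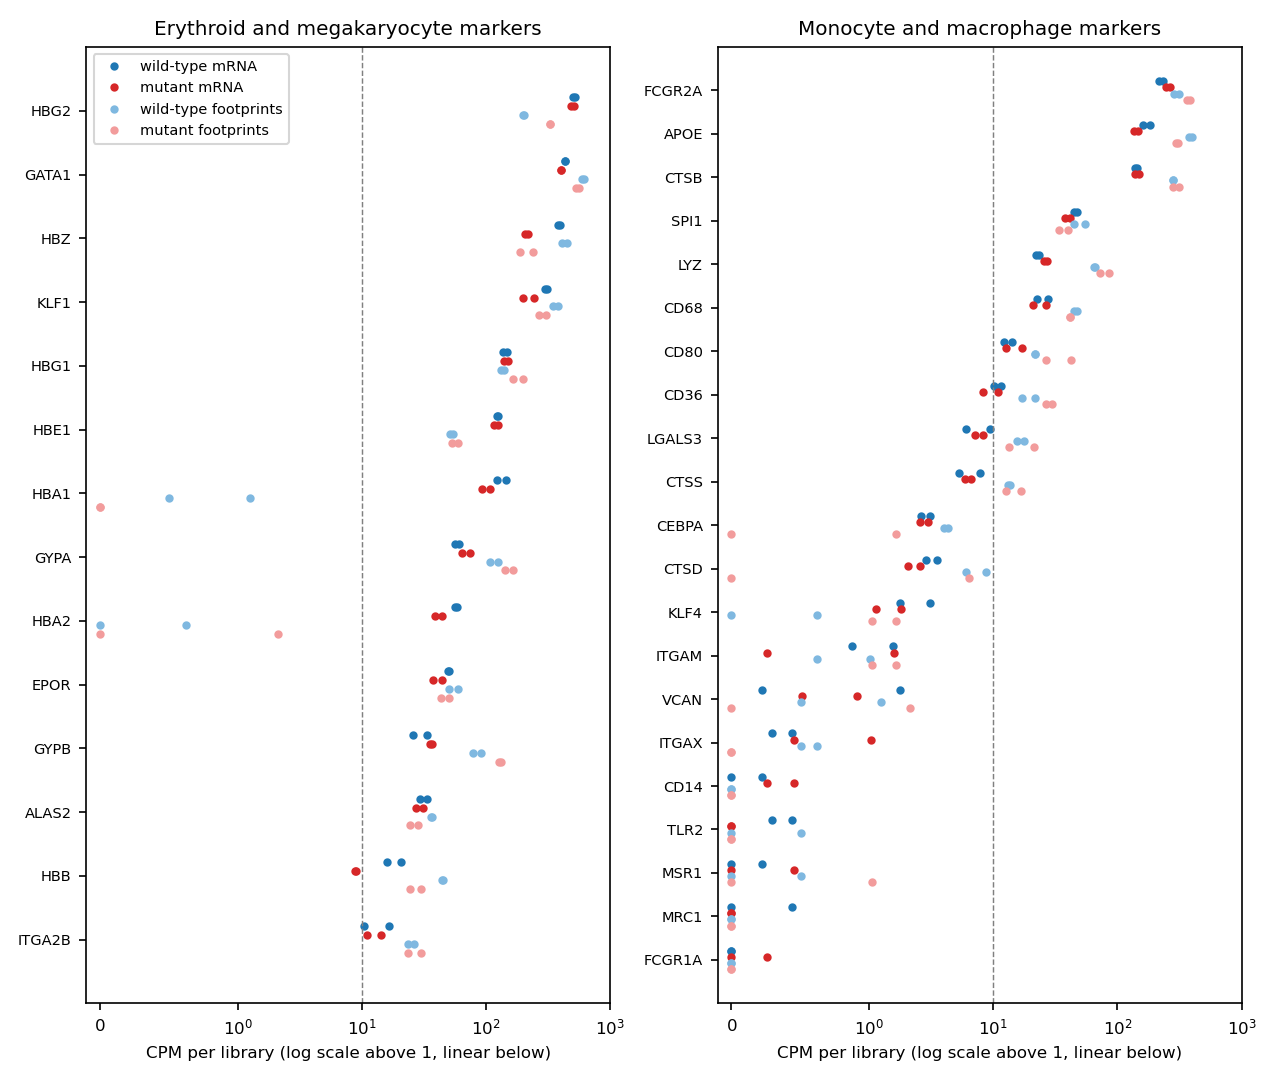
CPM of each erythroid and megakaryocyte marker (left) and each monocyte and macrophage marker (right) that had a count in at least 1 mRNA library, 1 point per library, on an axis that is logarithmic above 1 CPM and linear below; the dashed line marks 10 CPM. In each library 12 to 14 of 18 erythroid and megakaryocyte markers and 7 to 10 of 38 monocyte and macrophage markers reached that line.

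The first comparison asked how mRNA levels differed between mutant and wild type. The transcription factor ATF5 rose most among the named genes, 2.18-fold (log2 fold change 1.13, SE 0.133, edgeR adjusted p = 2.8e-15), from 21.6 ± 0.728 to 48.2 ± 2.61 CPM (ENSG00000169136, GRCh38 chromosome 19, 49928906 to 49933935). ALDH1L2, a mitochondrial enzyme of folate metabolism, rose from 25.6 ± 0.602 to 55.1 ± 8.34 CPM (edgeR adjusted p = 2.3e-16). The centrosomal protein gene CEP70 rose from 22.4 ± 2.34 to 44.8 ± 10.1 CPM, and the adhesion molecule gene NCAM2 from 21.8 ± 1.04 to 42.1 ± 0.0529 CPM. HBZ, the embryonic zeta globin, fell from 384 ± 12.4 to 211 ± 8.65 CPM (log2 fold change -0.90, SE 0.052, edgeR adjusted p = 2.2e-62; ENSG00000130656, GRCh38 chromosome 16, 152644 to 154503).

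The other genes named by size of change in mRNA were TATDN1, ZNF714, CCDC18 and TPRKB, which rose by log2 fold changes between 0.82 and 0.90. GLCCI1, the ubiquitin ligase gene TRIM35, the Dickkopf receptor gene KREMEN2, EVA1B, NDRG2, TMEM158 and the transcription factor gene TFAP2B fell by log2 fold changes between -0.89 and -0.77. All 16 of these genes kept their call and direction with each library left out, with DESeq2 and with an assumed biological coefficient of variation of 10%, while ATF5 and ALDH1L2 alone reached a 2-fold change.

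In all, 4060 of 10756 genes tested differed at an edgeR adjusted p under 0.05, with 2030 higher and 2030 lower in the mutant. The median size of a called change was 1.28-fold, and 74 of the calls reached 2-fold (48 higher, 26 lower). The replicates of a group differed little, with a common biological coefficient of variation of 2.25%, and the labels do not say that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. With an assumed coefficient of variation of 10%, a setting chosen after seeing the data, 313 genes were called (178 higher, 135 lower). DESeq2 called 1467. Without wild-type mRNA replicate 2 there were 2280 calls, and without mutant mRNA replicate 1 there were 2653.

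Genes of branched-chain amino acid (BCAA) catabolism, the pathway named in the study's title, were examined next. BCAT1, which transfers the amino group from leucine, isoleucine and valine, rose from 207 ± 5.38 to 264 ± 1.5 CPM (edgeR log2 fold change 0.32, adjusted p = 1.5e-07). DLD, the dehydrogenase subunit shared by the branched-chain and other 2-oxoacid complexes, rose from 143 ± 7.39 to 205 ± 12.4 CPM (log2 fold change 0.49, edgeR adjusted p = 5.3e-13), and ACAT1 rose too (log2 fold change 0.33). BCKDK, the kinase that inhibits the branched-chain 2-oxoacid dehydrogenase, fell from 123 ± 3.19 to 96.7 ± 5.03 CPM (log2 fold change -0.38, edgeR adjusted p = 5.1e-06). Of 29 measured members 9 rose, 2 fell and 18 were not called, with the same 9 and 2 when adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.0849; adjusted p = 0.431 with an estimated correlation), and none of its members was called with an assumed coefficient of variation of 10%. The call of BCKDK was lost once the trend with local gene density described below was removed, where its log2 fold change was -0.17.

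Amino acid transporters fell in mRNA. SLC7A5 and SLC3A2, which together form the LAT1 carrier of leucine and other large neutral amino acids, had log2 fold changes of -0.22 (edgeR adjusted p = 1e-06) and -0.32 (adjusted p = 6.8e-13), and the glutamine carriers SLC1A5 and SLC38A5 had -0.32 and -0.39. Of 19 measured members 11 fell, 2 rose and 6 were not called, with the same 11 and 2 when adjusted over the list alone. Camera called the list lower (adjusted p = 0.00638; adjusted p = 0.431 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose as a list: 15 of 23 members rose, 3 fell and 5 were not called, or 16 and 3 when adjusted over the list alone (camera adjusted p = 0.00218; adjusted p = 0.431 with an estimated correlation). EPRS1 rose from 369 ± 7.24 to 512 ± 2.85 CPM and YARS1 from 311 ± 2.65 to 401.3 ± 0.28 CPM, while VARS1 fell from 834 ± 15.3 to 682 ± 31.6 CPM and FARSA from 297 ± 1.81 to 214 ± 4.59 CPM. With an assumed coefficient of variation of 10% no transporter was called, and among the synthetases 1 fell and none rose.

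Lists of nutrient and stress signalling moved both ways. In the mTORC1 pathway list 5 of 39 members rose, 13 fell and 21 were not called, with the same 5 and 13 when adjusted over the list alone (camera adjusted p = 0.462; adjusted p = 0.577 with an estimated correlation). PDCD4, an inhibitor of translation initiation, rose from 45.6 ± 2.58 to 71.2 ± 1.54 CPM, and the leucine sensor SESN2 fell from 139 ± 2.96 to 108 ± 2.93 CPM. In the integrated stress response list 10 of 27 members rose, 10 fell and 7 were not called, or 10 and 11 when adjusted over the list alone (camera adjusted p = 0.808; adjusted p = 0.902 with an estimated correlation). Asparagine synthetase (ASNS) rose from 489 ± 10.9 to 686 ± 16.5 CPM, while DDIT4 fell from 851 ± 15.3 to 627 ± 19.2 CPM and GDF15 from 461 ± 7 to 356 ± 30.6 CPM. The median of this list was negative (-0.08) and its mean positive (0.02).

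Before the trend with local gene density was removed, mitotic genes gave the lowest p of any list in mRNA. CDK1, the kinase that drives entry into mitosis, rose from 136 ± 0.609 to 218 ± 0.662 CPM (edgeR log2 fold change 0.65, SE 0.063, adjusted p = 1.9e-22), and the kinetochore genes CENPE and CENPF and the topoisomerase gene TOP2A rose by 0.72, 0.52 and 0.35. In the G2/M list 19 of 30 members rose, 2 fell and 9 were not called, with the same 19 and 2 when adjusted over the list alone (camera adjusted p = 4.2e-06; adjusted p = 0.431 with an estimated correlation), and 7 rose with an assumed coefficient of variation of 10%. The S phase list was split, with 6 of 32 members higher, 8 lower and 18 not called, or 8 and 8 when adjusted over the list alone; MCM2, a subunit of the replicative helicase, fell from 180 ± 0.928 to 134 ± 5.99 CPM. Its median and mean were both 0.02 while camera gave a lower direction (adjusted p = 0.862; adjusted p = 0.91 with an estimated correlation).

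The lists of the translation machinery were higher in mRNA by small amounts. Of 79 cytosolic ribosomal protein genes 31 rose, 18 fell and 30 were not called, or 34 and 19 when adjusted over the list alone (camera adjusted p = 0.00223; adjusted p = 0.525 with an estimated correlation). RPL11 had a log2 fold change of 0.36 and RPS24 of 0.39, against -0.40 for RPS28. These genes have many near-identical pseudogene copies, so their counts are uncertain. Of 47 translation factor genes 19 rose, 8 fell and 20 were not called, or 19 and 9 when adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.431 with an estimated correlation): EIF3M and EIF3E rose by 0.40 and 0.34, and EIF4G1 fell, with -0.46. Camera gave the translation factors an adjusted p of 0.0644 without wild-type mRNA replicate 1. Once the density trend was removed, the ribosomal protein list had a median of 0.14 (camera adjusted p = 2.1e-29 at the preset correlation). The translation factors then had a camera adjusted p of 3.3e-05. Ribosomal protein genes took 10.1% ± 0.0649 of the counts in wild-type and 10.5% ± 0.2 in mutant mRNA libraries (exact permutation p = 0.333, two-sided, the smallest that 2 against 2 libraries allow).

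The chaperone of the endoplasmic reticulum HSPA5 (BiP) rose from 796 ± 6.1 to 1024 ± 6.23 CPM, and HERPUD1 and SEL1L of its degradation pathway had log2 fold changes of 0.39 and 0.55. In the unfolded protein response list 9 of 24 members rose, 2 fell and 13 were not called, with the same 9 and 2 when adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.431 with an estimated correlation), and the call was lost without wild-type mRNA replicate 1 (adjusted p = 0.0614). Whether reads of mitochondrially encoded genes were filtered out is not known here, so their share of counts need not measure transcript levels. Mitochondrially encoded genes took 0.0151% ± 0.00562 of wild-type and 0.022% ± 0.00798 of mutant mRNA counts (exact permutation p = 0.667, two-sided). Of 11 measured 8 rose, none fell and 3 were not called, or 10 and 0 when adjusted over the list alone, with a list median of 0.77 (camera adjusted p = 0.00481; adjusted p = 0.606 with an estimated correlation). This call was lost without wild-type mRNA replicate 2 or mutant mRNA replicate 1, with an adjusted p of up to 0.564.

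Lists of cholesterol and sugar metabolism were lower in the mutant. In cholesterol biosynthesis 8 of 24 members fell, 4 rose and 12 were not called, or 11 and 4 when adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.431 with an estimated correlation); without mutant mRNA replicate 2 the list had an adjusted p of 0.0742. The reductase DHCR7 fell from 263 ± 7.35 to 191 ± 8.16 CPM. Fatty acid synthase (FASN, ENSG00000169710) fell from 1991 ± 41.4 to 1268 ± 45.1 CPM (edgeR log2 fold change -0.68, SE 0.036, adjusted p = 7.4e-77). Its list of fatty acid synthesis and oxidation held 3 higher, 7 lower and 15 uncalled genes of 25, with the same 3 and 7 when adjusted over the list alone, and was not called (camera adjusted p = 0.199; adjusted p = 0.525 with an estimated correlation). In the glycolysis and hypoxia list 10 of 29 members fell, 1 rose and 18 were not called, with the same 10 and 1 when adjusted over the list alone (camera adjusted p = 0.00218; adjusted p = 0.431 with an estimated correlation). Pyruvate kinase (PKM) fell from 445 ± 7.67 to 322 ± 4.68 CPM, and the glucose carrier SLC2A1 from 304 ± 13.3 to 240 ± 17.9 CPM.

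Genes of the DNA methylation machinery were lower in the mutant: 10 of 19 fell, 1 rose and 8 were not called, with the same 10 and 1 when adjusted over the list alone. UHRF1, which recruits DNMT1 to replicated DNA, fell from 48.6 ± 0.0285 to 32.9 ± 0.482 CPM, the maintenance methyltransferase DNMT1 from 319 ± 4.79 to 272 ± 6.74 CPM and the 5-methylcytosine oxidase TET3 from 151 ± 4.89 to 122 ± 8.9 CPM. DNMT3A is itself a member. The list call was marginal (camera adjusted p = 0.0485; adjusted p = 0.431 with an estimated correlation) and was lost with each of the 4 mRNA libraries left out in turn (adjusted p of up to 0.0778) and with RLE factors (adjusted p = 0.0505).

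Replication-dependent histone transcripts, which lack poly(A) tails, summed to 22497 CPM in wild-type and 20770.4 CPM in mutant mRNA. Of 27 measured genes 15 fell, none rose and 12 were not called, with the same 15 and 0 when adjusted over the list alone (camera adjusted p = 0.00053; adjusted p = 0.431 with an estimated correlation). H2BC12 fell from 1699 ± 35.4 to 1482 ± 95.3 CPM, and H2AC6 and H1-4 had log2 fold changes of -0.31 and -0.23. Histone genes lie in dense clusters of near-identical copies, so their counts are uncertain, and the list's direction turned once the trend with local gene density was removed (median 0.11, camera adjusted p = 0.00185), where H1-4 stood at 0.02 and the call of H2AC6 was lost (-0.06).

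Erythroid and megakaryocyte markers were lower in mutant mRNA. Of 14 measured members 7 fell, none rose and 7 were not called, with the same 7 and 0 when adjusted over the list alone (camera adjusted p = 0.000698; adjusted p = 0.431 with an estimated correlation). Beside HBZ, the beta globin HBB fell from 18.4 ± 3.44 to 8.8 ± 0.115 CPM and KLF1 had a log2 fold change of -0.49. HBA1 fell from 134 ± 16.5 to 100 ± 9.77 CPM, though reads of HBA1 and its near-identical copy HBA2 may be exchanged. Epithelial markers fell as well: KRT19, KRT18 and KRT8 had log2 fold changes of -0.53, -0.38 and -0.34, while CLDN7 rose from 2.72 ± 0.714 to 5.24 ± 1.61 CPM. With 1 of 6 measured members higher, 3 lower and 2 not called, or 2 and 4 when adjusted over the list alone, camera called this list lower (adjusted p = 0.0105; adjusted p = 0.431 with an estimated correlation). The call of CLDN7 was lost without wild-type mRNA replicate 2 or mutant mRNA replicate 1 (adjusted p of up to 0.412). Both lists lost their call once the density trend was removed (camera adjusted p = 0.248 for the erythroid and 0.103 for the epithelial list). In footprints the erythroid list was not called: 4 of 12 measured members rose, HBG2 among them with a log2 fold change of 0.66, 4 fell and 4 were not called, or 4 and 5 when adjusted over the list alone (camera adjusted p = 0.517; adjusted p = 0.822 with an estimated correlation).

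**Figure D2:**
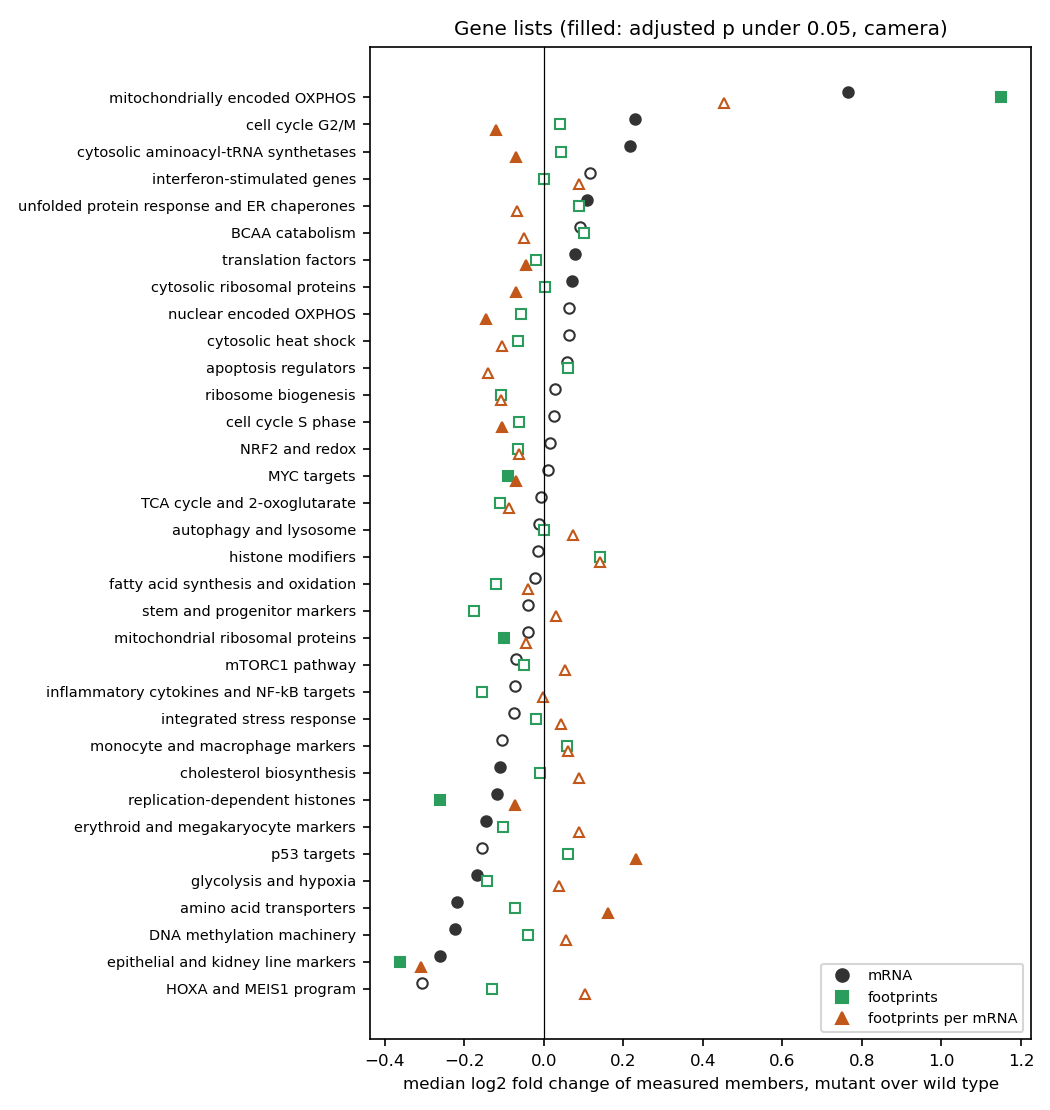
Median log2 fold change, mutant over wild type, of the measured members of each gene list, for mRNA (circles), footprints (squares) and footprints per mRNA (triangles); filled symbols passed camera with a preset correlation at an adjusted p under 0.05. The G2/M list lies at 0.23 in mRNA and the histone list at -0.26 in footprints, and no list passed with an estimated correlation.

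The size and sign of the mRNA changes followed how densely genes are packed around each gene. Across 10621 genes the mRNA log2 fold change was set against the number of protein-coding genes starting within 500 kb, the gene itself included. It had r = -0.38 with the log2 of this number plus 1, and r = 0.28 with the log2 of the gene's span. Genes are not independent replicates. Among the 1473 genes with a number of 1 to 5 the median was 0.18 and 73% were higher in the mutant. Among the 1043 genes with a number of 37 to 76 the median was -0.24 and 17.6% were higher. Footprint fold changes followed density with r = -0.25, and footprints per mRNA with r = 0.08. After the trend with density and span was removed in each library, a setting chosen after seeing the data, 2871 genes were called in mRNA, 2307 of them called before, with 2294 in the same direction.

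**Figure D3:**
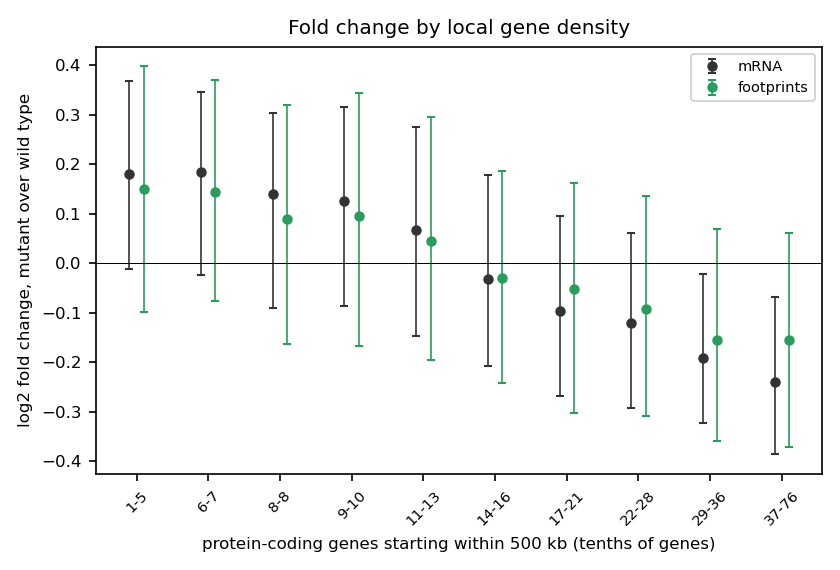
Median log2 fold change, mutant over wild type, of mRNA (black) and footprints (green) in 10 bins of genes ordered by the number of protein-coding genes that start within 500 kb; bars span the middle 50% of genes. The mRNA median passes from 0.18 in the sparsest bin to -0.24 in the densest.

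The second comparison asked how ribosome footprints differed. RPLP0, a ribosomal stalk protein, rose from 318 ± 16.8 to 623 ± 57.9 CPM (edgeR log2 fold change 0.94, SE 0.069, adjusted p = 9e-23; ENSG00000089157, GRCh38 chromosome 12, 120196699 to 120201111). The RNA helicase gene EIF4A2 rose from 85.1 ± 9.79 to 164 ± 6.53 CPM, the trypsinogen gene PRSS2 from 186 ± 18.1 to 346 ± 12.8 CPM, the topoisomerase gene TOP2B from 104 ± 8.67 to 192 ± 3.15 CPM and the tRNA exporter gene XPOT from 154 ± 0.869 to 284 ± 7.43 CPM. RPL13, a protein of the large ribosomal subunit, fell from 4796 ± 341 to 2416 ± 80.4 CPM (edgeR log2 fold change -1.05, SE 0.041, adjusted p = 5.2e-46). The ferritin heavy chain gene FTH1 fell from 122 ± 4.66 to 61.5 ± 9.13 CPM, HBZ from 428 ± 23.6 to 212 ± 37.9 CPM and the nucleolar protein gene NIFK from 168 ± 13.6 to 90.9 ± 2.76 CPM.

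The other named rises in footprints were those of ATP11B, LEPROT and ADGRV1, with log2 fold changes between 0.76 and 0.78. The other named falls were those of PIH1D1, the mRNA decay factor gene ZFP36L2 and the mitochondrial ribosomal protein genes MRPL2 and MRPS34, between -0.99 and -0.94. RPLP0, RPL13, FTH1, EIF4A2 and PRSS2 have near-identical copies elsewhere in the genome, and counts of such genes are uncertain for short footprints. Of these 16 genes 15 kept their call and direction with each library left out; the call of LEPROT was lost without mutant footprint replicate 1. All 16 were called with an assumed coefficient of variation of 10%.

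In all, 1950 of 9181 genes tested differed in footprints (945 higher, 1005 lower) at an edgeR adjusted p under 0.05, and 176 of them by at least 2-fold (94 higher, 82 lower). DESeq2 called 397, of which 33.5% were higher against 48.5% with edgeR. With an assumed coefficient of variation of 10% there were 288 calls (124 higher, 164 lower), and with all footprint libraries thinned to 603360 counts, 701. Without mutant footprint replicate 1 the count was 274, without mutant footprint replicate 2 it was 950, and without wild-type footprint replicate 2 it was 1155. Over all genes with a summed count of at least 20 the footprint replicates of a genotype differed by no more than sampling noise. The chi-square over its degrees of freedom was 1.01 in wild type (upper-tail p = 0.294) and 0.925 in mutant. A ratio under 1 means less spread than independent sampling gives, which this upper-tail test does not assess. Among genes with summed counts of 20 to 99 the replicates differed by less than that noise, with ratios of 0.868 in wild type and 0.899 in mutant. Among genes with a summed count of at least 1000 they did differ by the same chi-square test across genes (ratio 1.58, p = 5.5e-21, n = 710 genes in wild type; ratio 1.34, p = 0.00117, n = 192 genes in mutant). Each pair was kept as separate libraries, as labelled, since these ratios do not show whether the preparations were separate. If a pair came from a single preparation, n would be 1 and these p-values would not apply.

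Histone genes gave the lowest p of any list in footprints, and most of them fell. Of 26 measured histone genes 17 fell, 1 rose and 8 were not called, or 18 and 1 when adjusted over the list alone (camera adjusted p = 1.3e-19; adjusted p = 0.581 with an estimated correlation). H4C3 fell from 2229 ± 30.7 to 1495 ± 2.31 CPM, H4C2 from 1355 ± 38.2 to 929 ± 32.1 CPM and H3C10 from 1461 ± 28.1 to 1064 ± 4.34 CPM. With the density trend removed the list median moved from -0.26 to -0.004 and the call was lost (camera adjusted p = 0.812), while H4C3, H4C2 and H3C10 each kept theirs.

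Mitochondrial ribosomal proteins, which are encoded in the nucleus, fell as a list: 19 of 70 fell, 8 rose and 43 were not called, or 22 and 9 when adjusted over the list alone (camera adjusted p = 0.0391; adjusted p = 0.581 with an estimated correlation), MRPS34 and MRPL16 among them, with log2 fold changes of -0.94 and -0.82. This call was lost without wild-type footprint replicate 2 or mutant footprint replicate 1 (adjusted p of up to 0.0796) and with the density trend removed (adjusted p = 0.375). Of 8 measured mitochondrially encoded genes 5 rose, 1 fell and 2 were not called, with the same 5 and 1 when adjusted over the list alone (camera adjusted p = 0.0178; adjusted p = 0.581 with an estimated correlation). MT-ND4, a subunit of complex I, rose from 45.9 ± 7.97 to 113 ± 23.3 CPM (2.47-fold, edgeR adjusted p = 1.6e-11). Mitochondrially encoded genes took 0.0144% ± 0.0023 of wild-type and 0.0263% ± 0.00432 of mutant footprint counts. As in mRNA, it is not known whether their reads were filtered. The call of this list was lost without wild-type footprint replicate 2 or mutant footprint replicate 1, with an adjusted p of up to 0.093. Of 72 nuclear encoded genes of oxidative phosphorylation 12 rose, 23 fell and 37 were not called, or 16 and 24 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.172; adjusted p = 0.581 with an estimated correlation). NDUFB7 of complex I fell from 301.6 ± 0.93 to 171 ± 15.9 CPM.

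MYC footprints fell from 1348 ± 0.796 to 985 ± 29.6 CPM (edgeR log2 fold change -0.51, adjusted p = 4.1e-15), and the MYC target list held 9 lower, 3 higher and 18 uncalled genes of 30, or 9 and 4 when adjusted over the list alone. The prohibitin PHB1 and the helicase RUVBL2 were among those that fell, with -0.57 and -0.47. Camera called the list lower by a narrow margin (adjusted p = 0.0496; adjusted p = 0.581 with an estimated correlation), and the call was lost without wild-type footprint replicate 1 or mutant footprint replicate 2 (adjusted p of up to 0.114) and with the density trend removed (0.329). Epithelial markers fell in footprints too, with 4 of 6 lower, none higher and 2 not called, and the same 4 and 0 when adjusted over the list alone (camera adjusted p = 0.000453; adjusted p = 0.581 with an estimated correlation). KRT8 fell from 232 ± 12 to 141 ± 4.51 CPM and KRT19 from 376 ± 27.6 to 241 ± 5.81 CPM.

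The lists named for amino acids were not called in footprints. In BCAA catabolism 4 of 28 members rose, 1 fell and 23 were not called, or 2 and 1 when adjusted over the list alone (camera adjusted p = 0.348; adjusted p = 0.581 with an estimated correlation). DLD rose from 242 ± 22.8 to 385 ± 23.5 CPM, and BCAT1 had a log2 fold change of 0.18 (edgeR adjusted p = 0.0655). Of 18 amino acid transporters 3 rose, 1 fell and 14 were not called, or 4 and 2 when adjusted over the list alone; the list's median was -0.07, its mean 0.04 and its direction in camera higher (adjusted p = 0.942; adjusted p = 0.944 with an estimated correlation). Of 23 aminoacyl-tRNA synthetases 7 rose, 4 fell and 12 were not called, with the same 7 and 4 when adjusted over the list alone (camera adjusted p = 0.364; adjusted p = 0.822 with an estimated correlation). FARSA fell from 350 ± 21.3 to 250 ± 8.84 CPM. In the integrated stress response list 8 of 27 rose, 8 fell and 11 were not called, with the same 8 and 8 when adjusted over the list alone, and in the mTORC1 list 4 of 35 rose, 3 fell and 28 were not called, with the same 4 and 3 when adjusted over the list alone (camera adjusted p = 0.855 for each; adjusted p = 0.899 for each with an estimated correlation). Medians and means of both lists differed in sign. DDIT4 fell from 1540.2 ± 4.06 to 1146 ± 97.2 CPM, and ASNS rose from 836 ± 34.1 to 1089 ± 18.5 CPM.

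Cytosolic ribosomal protein genes moved apart in footprints: of 71 measured, 21 rose, 24 fell and 26 were not called, or 22 and 25 when adjusted over the list alone. RPS19 fell from 2706 ± 37.1 to 1558 ± 13.8 CPM and RPS13 from 942 ± 36.6 to 609 ± 39.2 CPM. The list's median was 0.003 and its mean 0.03, while camera gave a lower direction (adjusted p = 0.101; adjusted p = 0.581 with an estimated correlation), called only without wild-type footprint replicate 1 among the left-out libraries (0.0117). Their share of footprint counts was 5.67% ± 0.102 in wild-type and 5.29% ± 0.022 in mutant libraries (exact permutation p = 0.333, two-sided, the smallest possible here), a difference of -0.38 points, which was -0.186 points without the 10 genes with the most counts.

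Footprint and mRNA changes were compared across the 9166 genes measured in both assays, whose libraries are separate. The log2 fold changes had Pearson r = 0.48 and Spearman rho = 0.51 across genes, which are not independent replicates, and 70% of genes had the same sign. Among the 3068 genes with a mean count of at least 100 in each assay r was 0.63. Both assays called 577 genes higher, where independent lists would share 194, and 578 lower, where they would share 214; HBZ, MYC and FASN fell and CDK1, DLD and ASNS rose in both. Only 68 genes were called in opposite directions, 44 with higher mRNA and lower footprints (206 for independent lists) and 24 the other way (202). Without mutant footprint replicate 1 r was 0.36.

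**Figure D4:**
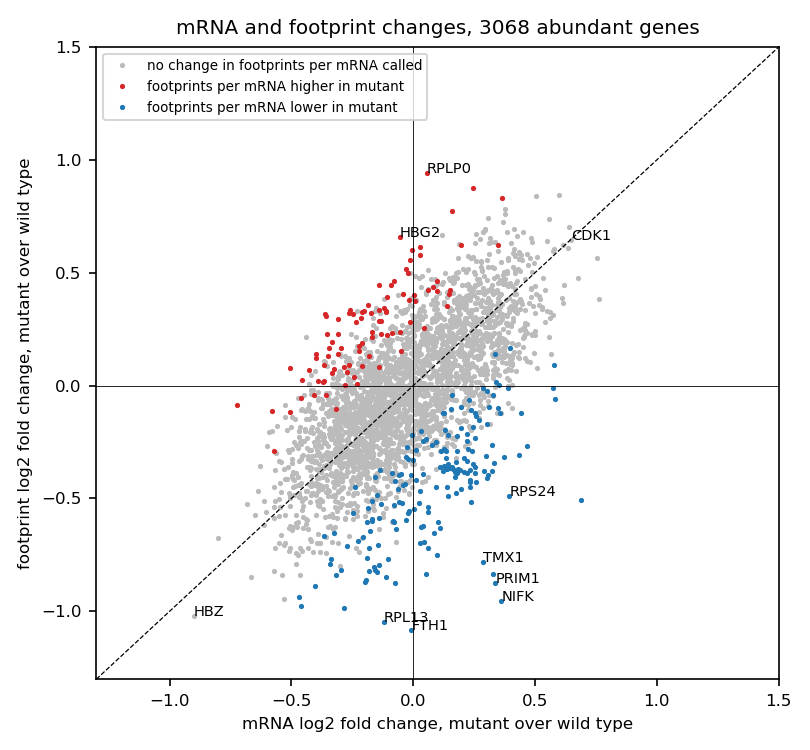
Log2 fold change of footprints against that of mRNA, mutant over wild type, for the 3068 genes with a mean count of at least 100 in each assay; the dashed line marks equal change, and colours mark genes whose footprints per mRNA were called higher (red) or lower (blue). Across these genes r = 0.63, and RPL13, NIFK and PRIM1 lie below the line and RPLP0 above it.

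The third comparison asked which genes changed in footprints per mRNA, the usual measure of translational efficiency, tested as the interaction of genotype and assay over all 8 libraries. RPLP0 rose 1.84-fold (edgeR log2 fold change 0.88, SE 0.079, adjusted p = 3e-14), with little change in its mRNA, which was 4157 ± 36.3 and 4409 ± 85.1 CPM. NIFK fell to 0.4 of its wild-type value (edgeR log2 fold change -1.32, SE 0.155, adjusted p = 1.1e-09; ENSG00000155438, GRCh38 chromosome 2, 121726945 to 121736875), as its mRNA rose from 56 ± 0.168 to 73.4 ± 4.42 CPM while its footprints fell. The DNA primase gene PRIM1 fell by a log2 fold change of -1.22 (adjusted p = 3.3e-08), with mRNA going from 65.7 ± 0.942 to 84.4 ± 12.4 CPM and footprints from 152 ± 3.71 to 86.9 ± 6.08 CPM. The splicing factor gene LSM3 had -1.17, FTH1 -1.08, the thioredoxin-related gene TMX1 -1.07 and RPL13 -0.93. Fetal globin HBG2 rose by 0.71 (adjusted p = 9e-08), its footprints going from 200 ± 4.43 to 326 ± 2.3 CPM, though its near-identical copy HBG1 makes this uncertain.

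The other named rises in footprints per mRNA were those of LENG8, SH2B3, NR2F6, EIF4A2, LEPROT and MRPL35 (0.60 to 0.68), and the other named falls those of ABRAXAS1 (-1.20) and EXOSC1 (-0.89). Of these 16 genes 10 kept their call with each library left out. LEPROT lost it without each library in turn except mutant mRNA replicate 1 (edgeR adjusted p of up to 0.318). MRPL35 lost it without wild-type mRNA replicate 2 or mutant footprint replicate 1 (up to 0.259), and SH2B3 without replicate 1 of either footprint group (up to 0.229). EXOSC1 lost it without mutant footprint replicate 1 (0.0848), and LENG8 and NR2F6 without mutant footprint replicate 2 (0.109 and 0.221). With an assumed coefficient of variation of 10% 8 of the 16 were called: RPLP0, NIFK, PRIM1, ABRAXAS1, LSM3, FTH1, TMX1 and RPL13.

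In all, 381 of 9166 genes were called (153 higher, 228 lower), 50 of them by at least 2-fold, and 1557 had an unadjusted p under 0.05. DESeq2 called 123. With an assumed coefficient of variation of 10% 13 genes were called, and without mutant footprint replicate 1 or 2 the count was 142 or 229. A limma test of the ratio of footprints to mRNA per replicate number called 0 genes, with 1254 at an unadjusted p under 0.05; on simulated data with a coefficient of variation of 2% the same test recovered 0 of 47 genes changed 2-fold.

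Cytosolic ribosomal protein genes held the most calls of any list. Of 71 measured 20 fell, 8 rose and 43 were not called, or 21 and 13 when adjusted over the list alone (camera adjusted p = 3.8e-08; adjusted p = 0.251 with an estimated correlation). RPS24 fell with -0.89 (SE 0.064, edgeR adjusted p = 1.7e-18) as its mRNA rose from 807 ± 14.5 to 1082 ± 46.4 CPM and its footprints fell from 1274 ± 61.6 to 935 ± 23.6 CPM; RPS19 fell with -0.74. Among translation factors 6 of 45 fell, 1 rose and 38 were not called, or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.0108; adjusted p = 0.251 with an estimated correlation): EIF4H, EIF3L and EIF3E had -0.67, -0.46 and -0.33, and EIF4A2 was the gene that rose. Of 26 histone genes 10 fell, 2 rose and 14 were not called, or 11 and 2 when adjusted over the list alone (camera adjusted p = 3.8e-08; adjusted p = 0.251 with an estimated correlation), with H4C3 at -0.67 and H2AC6, whose mRNA fell, at 0.53. Of 72 nuclear encoded genes of oxidative phosphorylation 13 fell, 4 rose and 55 were not called, or 17 and 5 when adjusted over the list alone (camera adjusted p = 0.000118; adjusted p = 0.251 with an estimated correlation). COX7B and COX5B of complex IV had -0.71 and -0.52, ATP5PF of the ATP synthase had -0.66 and ATP5MC2 had 0.43.

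Amino acid transporters were higher in footprints per mRNA. Of 18 measured 2 rose, none fell and 16 were not called, or 3 and 0 when adjusted over the list alone (camera adjusted p = 0.00177; adjusted p = 0.251 with an estimated correlation). The 2 that rose were SLC38A5 (0.40, edgeR adjusted p = 0.00085) and SLC1A5 (0.21, adjusted p = 0.025), whose mRNA fell while their footprints went from 516 ± 9.63 to 540 ± 18 CPM and from 1858 ± 7.04 to 1796 ± 37.8 CPM. SLC38A5 lost its call without mutant footprint replicate 1 (0.0748), and SLC1A5 without wild-type mRNA replicate 2, mutant mRNA replicate 1 or either mutant footprint replicate (up to 0.175). In BCAA catabolism HSD17B10 rose (0.40, edgeR adjusted p = 0.031) and 27 of 28 members were not called, or 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.524; adjusted p = 0.567 with an estimated correlation). The call of HSD17B10 was lost without wild-type mRNA replicate 2, mutant mRNA replicate 1 or replicate 1 of either footprint group (adjusted p of up to 0.387).

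Further lists passed camera in footprints per mRNA with few called members. The p53 target list was higher (2 of 18 rose, none fell, and 2 and 0 when adjusted over the list alone; camera adjusted p = 0.0246; adjusted p = 0.251 with an estimated correlation), and it was lost without mutant mRNA replicate 2 or mutant footprint replicate 2 (up to 0.187). The MYC target list was lower (2 of 30 fell, none rose, or 3 and 0 when adjusted over the list alone; camera adjusted p = 0.0246; adjusted p = 0.251 with an estimated correlation), and it was lost without wild-type footprint replicate 1 or mutant footprint replicate 2 (up to 0.071). The aminoacyl-tRNA synthetases were lower (1 of 23 fell, none rose, or 2 and 0 when adjusted over the list alone; camera adjusted p = 0.0354; adjusted p = 0.35 with an estimated correlation), as was the G2/M list (1 of 30 fell, none rose, or 3 and 1 when adjusted over the list alone; camera adjusted p = 0.0454; adjusted p = 0.251 with an estimated correlation). Both were lost without wild-type mRNA replicate 2, mutant mRNA replicate 1, wild-type footprint replicate 1 or mutant footprint replicate 2 (up to 0.187 and 0.122). The S phase list was lower, with PRIM1 and PCNA the 2 of 32 that fell and none higher, or 3 and 1 when adjusted over the list alone (camera adjusted p = 0.0354; adjusted p = 0.251 with an estimated correlation), and it was lost without mutant mRNA replicate 1, wild-type footprint replicate 1 or mutant footprint replicate 2 (up to 0.108). Epithelial markers were lower too (2 of 6 fell, none rose, with the same 2 and 0 when adjusted over the list alone; camera adjusted p = 0.0234; adjusted p = 0.251 with an estimated correlation), and were lost without mutant mRNA replicate 1, wild-type footprint replicate 2 or mutant footprint replicate 1 (up to 0.0596). With the density trend removed the S phase and G2/M lists were not called (camera adjusted p = 0.0749 and 0.151).

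In the nutrient signalling lists few genes changed in footprints per mRNA. Of 27 genes of the integrated stress response MTHFD2, a mitochondrial folate enzyme, fell (-0.52, edgeR adjusted p = 1.9e-08), ATF4, its transcription factor, fell (-0.58, adjusted p = 0.028) and 1 rose, or 2 and 2 when adjusted over the list alone (camera adjusted p = 0.886; adjusted p = 0.876 with an estimated correlation). Of 35 mTORC1 pathway genes SESN2 (0.54) and the translational repressor EIF4EBP1 (0.56) rose and none fell, or 3 and 0 when adjusted over the list alone (camera adjusted p = 0.323; adjusted p = 0.384 with an estimated correlation). ATF4 lost its call without wild-type footprint replicate 2 or either mutant footprint replicate (adjusted p of up to 0.238), SESN2 without mutant footprint replicate 2 (0.282), and EIF4EBP1 without wild-type mRNA replicate 2 or mutant footprint replicate 1 (up to 0.182). None of the 4 genes was called with an assumed coefficient of variation of 10%.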

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

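The comparison of directions was chosen only after the mRNA and footprint results were seen. Among the 9166 genes measured in both assays, 68 were called in opposite directions in mRNA and in footprints, and each was also called in the test of footprints per mRNA. The genes were picked for their opposite calls, which by itself favours a call in that test. With an assumed coefficient of variation of 10% only 7 of the 68 kept that call, RPS24, NIFK and PRIM1 among them. In 44 of them mRNA was higher and footprints were lower. RPS24 had log2 fold changes of 0.39 in mRNA and -0.49 in footprints, NIFK 0.36 and -0.96, PRIM1 0.34 and -0.88, MTHFD2 0.18 and -0.34, and the microtubule regulator gene STMN1 0.17 and -0.40. In the other 24 mRNA was lower and footprints were higher, among them H2AC6 (-0.31 and 0.23) and RPL35 (-0.12 and 0.34).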

How the results depend on the processing

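The assumed coefficient of variation, the removal of the density trend and the thinning of footprint libraries were chosen only after the results were seen. The numbers of calls depended on the setting, and where no cause is named the cause was not tested. The mRNA calls (4060) fell to 1467 with DESeq2, 313 with an assumed coefficient of variation of 10% and 74 with a 2-fold threshold, and ranged from 2280 to 3838 with 1 library left out. The footprint calls (1950) fell to 397 with DESeq2, 1274 with a mean count of at least 100 (fewer genes tested), 288 with the assumed variation, 701 after thinning (fewer counts) and 176 with a 2-fold threshold, and ranged from 274 to 1799 with 1 library left out. The calls in footprints per mRNA (381) were 123 with DESeq2, 0 with the limma test of paired ratios (1254 at an unadjusted p under 0.05), 13 with the assumed variation, 184 after thinning and 50 with a 2-fold threshold, and ranged from 142 to 448 with 1 library left out. With upper-quartile factors 57.2% of mRNA calls were higher, against 50% with TMM.

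The labels do not say whether a replicate number marks a shared batch: deviations of same-numbered libraries correlated at 0.0295 to 0.209 across 3068 genes, all positive. With the replicate number as a block there were 4168 mRNA calls, 2076 footprint calls and 546 calls in footprints per mRNA, and with a replicate block within genotype 598. Under the block the DNA methylation list was not called in mRNA (adjusted p = 0.054), and cytosolic ribosomal proteins (0.0151) and glycolysis (0.0305) were called in footprints. The block changed no other list call.

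Of the called lists, 13 in mRNA, 5 in footprints and 11 in footprints per mRNA, 0, 0 and 0 passed with an estimated correlation in camera. With fry 14, 0 and 6 lists passed, of which 10, 0 and 4 were called in the same direction before. With the density trend removed 13, 2 and 9 passed, of which 10, 2 and 9 were called in the same direction before. With 1 library left out 10 to 11, 3 to 5 and 6 to 11 lists passed, not always the same ones. The histone list in mRNA turned from lower to higher once the trend was removed (adjusted p = 0.00185). So did H1-4 and IFITM1 in mRNA, with log2 fold changes of 0.0211 and 0.0873 after removal. LAPTM4B in footprints turned from higher to lower, with a log2 fold change of -0.0146. None of the 3 was called after removal.

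The mRNA log2 fold change of DNMT3A was -0.271 and not called with the assumed variation. In footprints its value lay near 0 and changed sign: 0.00367 with DESeq2, 0.00748 with upper-quartile factors, 0.042 with a mean count of at least 100, 0.017 with the replicate block, 0.00499 with the assumed variation, and from -0.079 to 0.0841 with 1 library left out. With the density trend removed it was farthest from 0, at -0.147 and not called, and the mRNA value was -0.412 and called. The correlation of mRNA and footprint changes (0.48) was 0.628 with a mean count of at least 100 and 0.409 after removal of the trend, and ranged from 0.356 to 0.511 with 1 library left out. The footprint share of ribosomal proteins differed by -0.186 points without the 10 genes with the most counts, against -0.38 with them.

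With the assumed variation 95 of 138 named mRNA genes, 76 of 131 named footprint genes and 62 of 71 genes named in footprints per mRNA lost their call. Over all settings run, 1743 of 1910 combinations of a named gene and a setting kept direction and call in mRNA, 1645 of 1910 in footprints and 1185 of 1531 in footprints per mRNA. Most of the rest lost the call in the same direction (165, 264 and 346). Of named footprint genes 33 of 128 lost their call after thinning and 67 of 131 without mutant footprint replicate 1. In footprints DESeq2 gave no adjusted p for 5874 genes.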

Other observations

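Of the tests of explanations in this part, all but the thinning of the mRNA libraries and the test of near-identical copies were chosen only after the results were seen, while the edgeR and camera tests were planned. Pyruvate carboxylase (PC), which replenishes the citric acid cycle, fell in mRNA from 75.2 ± 0.313 to 46.1 ± 0.735 CPM (edgeR log2 fold change -0.73, adjusted p = 8.5e-12). Its list of the citric acid cycle and 2-oxoglutarate metabolism held 3 higher, 5 lower and 20 uncalled genes of 28 in mRNA, or 2 and 4 when adjusted over the list alone (camera adjusted p = 0.704; adjusted p = 0.902 with an estimated correlation). Footprints of GPX4, which reduces lipid peroxides, fell from 892 ± 80 to 540 ± 66.1 CPM (edgeR adjusted p = 1.2e-20), and footprints per mRNA fell too (log2 fold change -0.65, adjusted p = 2.1e-08). The NRF2 and redox list was not called in footprints per mRNA, with 2 of 19 higher, 3 lower and 14 not called, or 3 and 4 when adjusted over the list alone (camera adjusted p = 0.12; adjusted p = 0.251 with an estimated correlation).

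XIAP, a caspase inhibitor, rose in mRNA from 16.8 ± 0.645 to 30.9 ± 0.886 CPM (edgeR adjusted p = 1.1e-06). Its list of apoptosis regulators had 5 of 21 higher, 1 lower and 15 not called, with the same 5 and 1 when adjusted over the list alone (camera adjusted p = 0.428; adjusted p = 0.577 with an estimated correlation). The small heat shock protein HSPB1 fell in mRNA from 532 ± 19.5 to 392 ± 13.9 CPM and in footprints from 610 ± 43.3 to 416 ± 35.6 CPM (edgeR adjusted p = 4.8e-23 and 9.6e-13). In mRNA 6 of 17 cytosolic heat shock genes rose, 3 fell and 8 were not called, or 6 and 4 when adjusted over the list alone (camera adjusted p = 0.91; adjusted p = 0.943 with an estimated correlation).

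Erythroid markers were abundant and most monocyte markers near 0 in all 8 libraries labelled THP-1. A mixture of monocytic with erythroid cells would bring the abundant monocyte transcripts. In the mRNA mean 8 of 38 monocyte and macrophage markers reached 10 CPM, fewer than the 19 a mixture was taken to need. A small share of monocytic cells could also leave markers under 10 CPM, so this test could not exclude a mixture. An effect of the DNMT3A mutant is argued against by 14 of 18 erythroid and megakaryocyte markers at 10 CPM or more in the wild-type mRNA libraries; an effect of transduction itself was not tested, as no untransduced cells were analysed here. A candidate explanation is that the libraries came from an erythroid line under a monocytic label, which required at least 9 of the 18 markers at 10 CPM in each library; the fewest in any library was 12. This remains a hypothesis, since the same libraries raised it.

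The mRNA fold changes followed local gene density (r = -0.38). After the mRNA libraries were thinned to the same total r was -0.375. Thinning keeps each gene's expected share of the counts, so this test could not decide on unequal depth. The fitted trend in density and span as the whole cause of the mRNA calls is argued against, since 2294 calls were shared in direction after its removal. A bias that density and span follow only in part would leave such calls too, so removal of the trend does not test it. A composition bias that varies from library to library could remain: mutant mRNA replicates differed along density with r = -0.127, between the bounds set for and against it. An effect of the mutant on genes in gene-dense regions may also give the footprint correlation of -0.254, as would a bias shared by both assays. These explanations cannot be told apart with 2 libraries per group.

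Cytosolic ribosomal protein genes changed in footprints per mRNA in both directions. Of 71 measured members 8 were called higher and 20 lower, so the calls were not all falls. The counts of these genes are uncertain, so a fall in translation shared by most members is left open. The density trend is argued against by 25 of 28 calls that were shared in direction after its removal. Reads lost to near-identical copies could contribute: among 60 abundant members the change did not increase where wild-type footprints per mRNA were fewest (Spearman rho 0.179 across genes, permutation p = 0.17 with 10000 permutations), which lies on the other side of 0 from the prediction but does not differ from 0. The median size of change was 0.189 on the log2 scale among these members and 0.124 among other genes matched on abundance. Lost reads, a fall shared by most members and a change in the translation of single ribosomal protein genes cannot be told apart here.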
